A study of Mus musculus with 45 samples.

How the data were processed

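RNA of mouse brain tumours from a glioblastoma model was measured on Affymetrix 3' IVT arrays. Per the labels, total RNA was extracted with Trizol, 100 ng was labelled with biotin, and the strain was CD-1 nude. Per the series description, wild-type PDGFRA or 6 mutants affecting different regions of the receptor were delivered by retrovirus to primary mouse astrocytes lacking p53. The deposited values are log2 signals of probe sets, which the authors made with RMA, a method of background correction, quantile normalisation and probe set summary. No version or settings of RMA were stated. The table held 45141 probe sets for 45 arrays, with values from 1.46 to 13.82 and array medians from 4.66 to 4.85, and was taken as deposited. For arrays, the number of arrays limits the precision of each value.

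The 45 arrays were grouped by the genotype in the labels into 8 groups, and replicates were numbered in the order of the table. Numbers in the sample titles fell into 2 ranges, 1 to 30 with 21 arrays and 41 to 64 with 24 arrays. The labels do not state that these ranges are batches. All 8 EGFRvIII arrays, the 3 Pdgfra E7 del arrays and the Pdgfra WT array lay in the upper range, whereas the Pdgfra C450 ins, D842V and E10 del arrays lay in the lower range. The Pdgfra V544ins and E10 del.v2 groups had 3 arrays in the lower range and 6 in the upper. Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure the spread between these samples.

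Of the probe sets, 28898 matched 1 gene symbol, 551 matched several and 15692 matched none. For each of 17097 genes the probe set with the highest mean over all arrays was used, and genes above the table median of 4.79 in at least 3 arrays were kept, which left 11827. Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 8 groups, without covariates, and contrasts of group means were tested. The mutants were compared with EGFRvIII by the unweighted mean of the 6 mutant group means, and each mutant with the unweighted mean of the other 5. Differences among the 6 mutants were tested with limma's moderated F test. The title number ranges were compared within the 18 arrays of the 2 groups that span both. P-values were adjusted by the Benjamini-Hochberg method over all genes kept, and an adjusted p under 0.05 was called.

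The groups, comparisons, filter, named-gene rule, gene lists and the alternative settings not named below as later additions were chosen before the data were examined. Named genes were, against EGFRvIII, the 10 called genes with the largest difference in each direction whose 6 mutant means all lay on the same side of EGFRvIII. For each other contrast they were the 5 with the largest difference in each direction, and for the F test the 10 with the smallest p. Predicted and clone genes were passed over. Pdgfra, Egfr and the sex chromosome genes were always included, as were up to 4 members with the smallest p of a list described in the text. Trp53 was not analysed here.

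The 29 gene lists held 504 symbols, 395 of them among the kept genes, and were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Alternatives were camera with an estimated correlation and fry, which tests whether the members move one way on balance and does not compare them with other genes. Other alternative settings were no filter, a filter of 9 arrays, the mean of all probe sets of a gene, centred arrays, quantile normalisation, a trended robust prior and array weights. The rest were the title number range as a fixed block, either range alone, a host brain covariate (the mean of the neuron and myelinating oligodendrocyte lists), all mutant arrays as 1 group, only the arrays compared, a minimum log2 difference of 1, and leaving out each array. Chosen after seeing the data were the neuron list alone as a covariate and fits without 4 or 3 arrays that stood apart on principal components 1 and 2, the latter also within titles 41 to 64.

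The procedure was tested on simulated data, normal values with the mean and residual spread of each gene, independent between genes, of which 200 genes were changed by known amounts. For the mutants against EGFRvIII it recovered 38% of changes of 0.5 on the log2 scale, 74% of changes of 1 and 88% of changes of 2, and 4.5% of its calls were false. For Pdgfra E7 del the recovered shares were 12%, 48% and 80%, with 5.6% false calls. For Pdgfra E10 del 7.7% of the calls were false. The simulated arrays lacked the shared differences between samples of the real ones, where principal component 1 held 41% of the variance. These shares therefore need not hold for the real arrays.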

Results

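Tumours of 8 genotypes were profiled on 45 arrays. EGFRvIII, the truncated and constitutively active epidermal growth factor receptor, gave 8 arrays. The PDGFRA mutants, named as in the labels, were V544ins and E10 del.v2 with 9 arrays each, C450 ins, D842V and E10 del with 5 each, and E7 del with 3. The unmutated receptor gave 1 array, reported as values without a test. Values are log2 signals, errors of differences are standard errors of the limma fit, and errors of group levels are SD. The arrays differed most in their content of neuronal transcripts. Group means of the neuron list ran from 6.31 ± 1.91 in E7 del (n = 3) to 9.64 ± 1.18 in E10 del (n = 5), with 7.24 ± 1.61 in EGFRvIII (n = 8). Component 1 of a principal component analysis held 41% of the variance and component 2 held 13.7%. The E10 del group had the lowest median score on component 1, -90.4, and E7 del the highest, 49.3. The 4 arrays lowest on component 1 were E10 del replicates 1, 2 and 3 and E10 del.v2 replicate 2. The log2 difference between the 3' and 5' probe sets of Actb, a sign of RNA integrity, had group means from 0.58 to 0.74. It was 1.19 in E10 del.v2 replicate 2, and 0.70, 0.93 and 0.91 in E10 del replicates 1, 2 and 3 against 0.56 and 0.60 in replicates 4 and 5. The same measure of Gapdh was -0.05 in D842V and 0.10 to 0.23 in the other replicated groups.

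**Figure D1:**
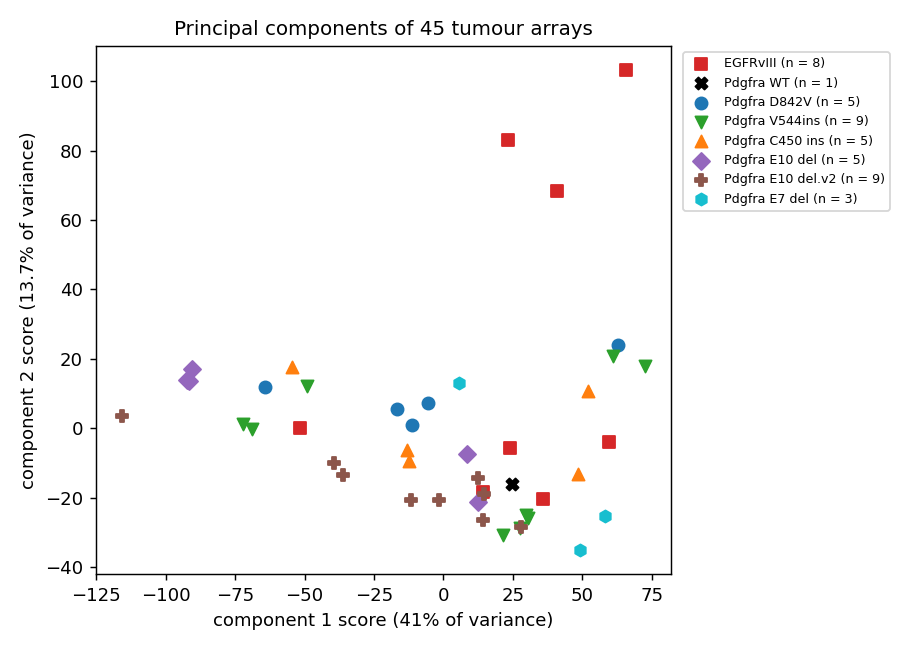
Scores of the 45 arrays on principal components 1 (41% of variance) and 2 (13.7% of variance), in arbitrary units, with a marker for each group. EGFRvIII replicates 4, 5 and 6 lie at the top with component 2 scores of 83.1, 103.3 and 68.3, and 3 E10 del arrays and E10 del.v2 replicate 2 lie at the left with component 1 scores from -115.8 to -90.4.

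The comparison of the 6 PDGFRA mutants with EGFRvIII asked how tumours driven by mutant PDGFRA differed from those driven by another receptor. In the PDGFRA tumours Grik3, a kainate-type glutamate receptor subunit, was 5.88-fold higher (log2 difference 2.56 ± 0.34, adjusted p = 1.39e-05), with group means from 8.04 to 8.64 in the mutants against 5.82 ± 1.82 in EGFRvIII (n = 8). St6gal2, a sialyltransferase, rose 6.25-fold (2.64 ± 0.49, adjusted p = 0.00126), and the synaptic vesicle gene Synpr and the cyclin-dependent kinase inhibitor Cdkn1c rose 3.78-fold and 5.07-fold. Capn6, Ly6h, Pisd-ps3 and Zfp711 rose by 2.62, 2.23, 1.92 and 1.86 on the log2 scale.

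Arg1, the arginase made by alternatively activated macrophages among other cells, was 9.47-fold lower (log2 difference -3.24 ± 0.68, adjusted p = 0.00367), and the acute phase gene Saa3 was 4.93-fold lower. Arg1 was 11.53, 10.97 and 7.93 in EGFRvIII replicates 4, 5 and 6 and 3.43 to 7.18 in the other 5. Its difference was -1.32 ± 0.62 without those 3 arrays (adjusted p = 0.489) and -3.74 to -2.59 when 1 array at a time was left out. Ltbp1, which binds latent TGF-beta, fell 7.02-fold (-2.81 ± 0.39, adjusted p = 2.79e-05). The embryonic chromatin protein gene Hmga2 fell 6.72-fold (-2.75 ± 0.44, adjusted p = 0.000206) and the mesenchymal transcription factor gene Twist1 fell 4.65-fold (-2.22 ± 0.37, adjusted p = 0.000325). Cdkn2b, an inhibitor of CDK4 and CDK6, was 4.81-fold lower (-2.27 ± 0.35, adjusted p = 8.85e-05), at 9.44 ± 1.1 in EGFRvIII (n = 8) and 6.01 to 7.95 in the mutant means. Mgst2, Adh7, Ear3 and the class II histocompatibility gene H2-Eb1 were lower, with log2 differences of -2.29, -2.27, -2.19 and -2.15. In all, 1061 of 11827 genes were called, 423 higher and 638 lower in the PDGFRA tumours, and 291 of them differed at least 2-fold.

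The MAPK feedback and output list, genes induced by signalling through ERK, some of which restrain it, was lower in the PDGFRA tumours. Of its 20 measured members 7 fell, 0 rose and 13 did not pass, and 12 fell when adjusted over the list alone (camera adjusted p = 1.74e-05, adjusted p = 0.248 with an estimated correlation). The ERK phosphatase gene Dusp6 had a log2 difference of -0.89 ± 0.18, Epha2 -1.12 ± 0.24, the pathway inhibitor gene Spry4 -1.29 ± 0.28 and the AP-1 gene Fosl1 -1.64 ± 0.38. Within titles 41 to 64 alone none of these 4 genes was called (adjusted p from 0.071 to 0.127), with differences of -0.67 ± 0.18, -1.17 ± 0.35, -1.17 ± 0.30 and -1.71 ± 0.55. Fry also called this list (adjusted p = 0.00031). Its mean was 8.48 ± 0.36 in EGFRvIII (n = 8) and 7.33 to 8.23 in the mutant groups. The list of FOXO targets that AKT represses was also lower, with 2 of 12 members fallen, 10 not passing and 3 fallen when adjusted over the list alone (camera adjusted p = 0.022, adjusted p = 0.248 with an estimated correlation, fry adjusted p = 0.00031). The fallen members were the insulin receptor gene Insr (-0.59 ± 0.09) and the proapoptotic gene Bcl2l11 (-0.87 ± 0.29). The FOXO list mean was 8.44, 8.89 and 8.85 in EGFRvIII replicates 4, 5 and 6 and 7.64 to 8.18 in the other 5.

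Markers of the mesenchymal subtype of glioma were lower in the PDGFRA tumours, with 5 of 25 members fallen, 20 not passing and 8 fallen when adjusted over the list alone (camera adjusted p = 0.000159, adjusted p = 0.791 with an estimated correlation). The members with the smallest p were Anxa1 (-2.02 ± 0.59), Plaur (-1.25 ± 0.37), Casp1 (-1.34 ± 0.40) and Il4ra (-0.55 ± 0.17). The list mean was 9.85, 9.61 and 9.19 in EGFRvIII replicates 4, 5 and 6 and 6.58 to 8.2 in the other 5. Proneural markers were higher as a list (camera adjusted p = 0.0308, adjusted p = 0.791 with an estimated correlation), though only Stmn1 of 16 members rose (0.57 ± 0.17), also when adjusted over the list alone. Their mean was 8.32, 7.8 and 8.61 in these 3 EGFRvIII arrays and 9.57 to 10.15 in the other 5. Oligodendrocyte progenitor genes were higher as a list with 0 of 17 members passing in either adjustment (camera adjusted p = 0.0255, adjusted p = 0.791 with an estimated correlation), the smallest p belonging to Bcan (1.32 ± 0.47). Their mean was 7.12, 6.14 and 8.13 in the same 3 EGFRvIII arrays and 9.5 to 10.77 in the other 5. Neuron and myelinating oligodendrocyte markers were higher as lists (camera adjusted p = 0.00604 and 0.0165). In them 1 of 18 members rose in each, Snap91 (1.0 ± 0.31) and Fa2h (1.26 ± 0.37), and 1 and 4 rose when adjusted over the list alone (adjusted p = 0.791 with an estimated correlation for both).

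The ependymal and choroid plexus list and the cholesterol synthesis list were higher with 0 members passing in either adjustment (camera adjusted p = 0.0308 and 0.0424). The NF-kB and inflammatory list and the unfolded protein response list were lower (camera adjusted p = 0.0308 for both). The NF-kB list mean was 8.09, 6.81 and 7.85 in EGFRvIII replicates 4, 5 and 6 and 5.09 to 6.26 in the other 5. Trib3 alone fell among the members of these 4 lists (-0.90 ± 0.28), and 4 of the 15 unfolded protein response genes fell when adjusted over the list alone. All 4 had adjusted p = 0.791 with an estimated correlation. The other 18 lists did not pass, with camera adjusted p from 0.0983 for classical glioma markers to 0.993 for interferon response. They covered astrocytes, microglia and macrophages, lymphocytes, granulocytes, endothelium, pericytes, fibroblasts, erythroid cells, neural stem cells, the cell cycle, immediate early genes, ERBB and PDGF ligands and receptors, hypoxia, Wnt and BMP targets and Hox genes.

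The probe sets used for the receptor genes did not pass between these groups. The log2 difference of Pdgfra was -0.43 ± 0.47 (adjusted p = 0.556), with 7.22 ± 1.75 in EGFRvIII (n = 8), and that of Egfr was -0.17 ± 0.37 (adjusted p = 0.793). Of the other 5 Egfr probe sets, which were not tested, 2 had 5.63 ± 0.26 and 3.83 ± 0.40 in EGFRvIII (n = 8), against mutant means of 4.89 to 5.31 and 3.25 to 3.51, and 5.75 and 3.31 in the array with unmutated PDGFRA. The remaining 3 had 5.19, 3.15 and 2.96 in EGFRvIII, against 4.41 to 5.6, 3.16 to 3.21 and 2.74 to 3.07. The labels do not say whether the probe sets detect the retroviral transcripts. The Y-linked genes Eif2s3y, Uty and Kdm5d were higher in the PDGFRA tumours by 2.61 ± 0.81, 2.28 ± 0.45 and 1.78 ± 0.58 (adjusted p = 0.0366, 0.00209 and 0.0451), and the X-inactivation transcript Xist was lower, with a difference of -0.92 ± 0.26 (adjusted p = 0.0224). Kdm5d lost its call in 22 of the 44 fits that left out 1 array, Eif2s3y in 5, Xist in 1 and Uty in 0. Uty stayed between 2.50 and 3.16 in all 8 EGFRvIII arrays.

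Since all EGFRvIII arrays had titles 41 to 64, the comparison was repeated with the title range as a block, which called 310 genes, 245 of the 1061 among them, and within that range alone, which called 79, 69 of them shared. Under the block 8 named genes lost their calls (adjusted p from 0.0607 to 0.381), with differences of 1.04 ± 0.61 for Synpr, -1.28 ± 0.73 for H2-Eb1, 1.75 ± 0.65 for Ly6h and -0.69 ± 0.23 for Dusp6. Those of the other 4 stayed about as large, at -2.37 ± 0.76 for Ear3, -1.62 ± 0.48 for Fosl1, 2.83 ± 1.03 for Eif2s3y and 1.99 ± 0.73 for Kdm5d. Synpr, Ear3 and H2-Eb1 also lost their calls with the host brain covariate (1.12, -1.89 and -1.53), and Ear3 without EGFRvIII replicate 4 or 5 (-1.45 and -1.38). Of the genes named above with the largest differences, Grik3, Capn6, Uty, Pisd-ps3, Arg1, Ltbp1, Hmga2, Cdkn2b and Twist1 were called within titles 41 to 64 alone. The count was 495 with the host brain covariate, 500, 186 and 331 without EGFRvIII replicate 4, 5 or 6 in turn, and 2245 without EGFRvIII replicate 1. Without replicates 4, 5 and 6 together 54 genes were called, where Grik3, Uty, Ltbp1, Adh7, Cdkn2b, Twist1 and Spry4 were the genes named above that were still called and the MAPK list kept its direction (camera adjusted p = 2.3e-05). With titles also restricted to 41 to 64, 0 of 22 named calls were kept, with differences from -0.45 for Mgst2 and -0.58 for Adh7 to -2.81 for Twist1, 2.34 for Pisd-ps3 and 4.09 for Eif2s3y. Without the 3 arrays the oligodendrocyte progenitor list turned (-0.55, camera adjusted p = 0.00115), as did the proneural, mesenchymal, NF-kB and cholesterol lists (camera adjusted p from 0.515 to 0.845). The myelinating oligodendrocyte, FOXO and unfolded protein response lists lost their calls (camera adjusted p = 0.785, 0.451 and 0.622). The neuron list had a median difference of -0.21 under the block (camera adjusted p = 0.818).

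**Figure D2:**
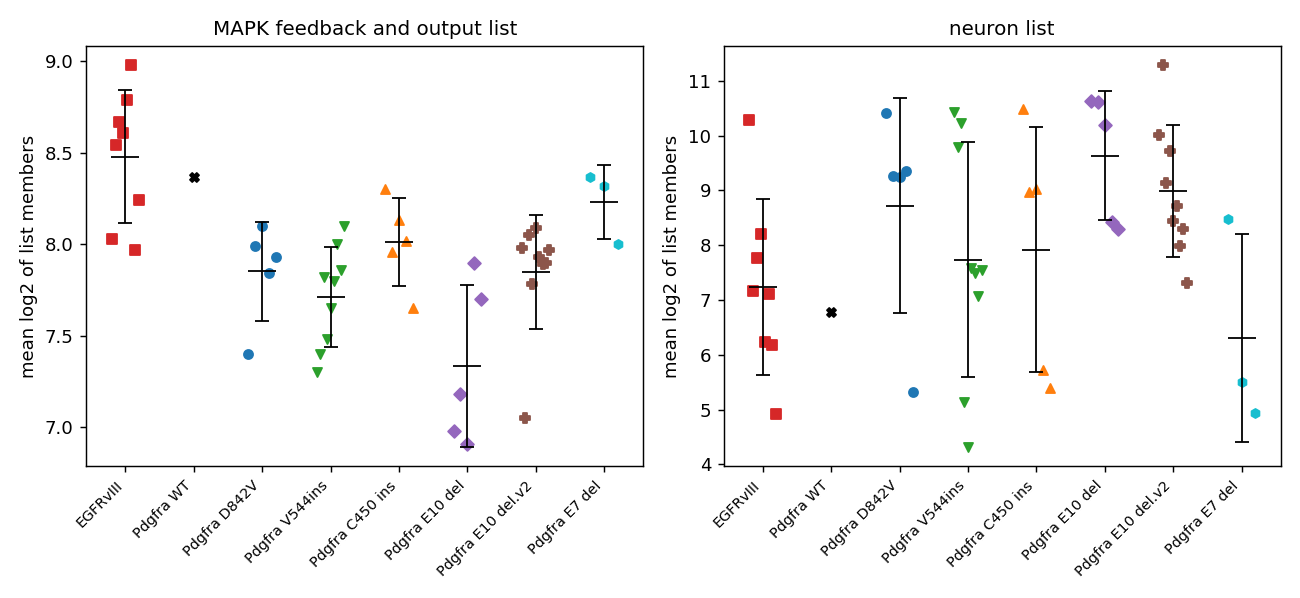
Mean log2 value per array of the MAPK feedback and output list (left) and of the neuron list (right) in each group, with 1 point per array and bars for the group mean and SD. MAPK list means were 8.48 in EGFRvIII and 7.33 to 8.23 in the mutant groups, and neuron list means ran from 6.31 in E7 del to 9.64 in E10 del.

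Whether the 6 mutants differed from each other was tested gene by gene, and 68 genes differed among them. The developmental transcription cofactor gene Eya2 had the smallest p (adjusted p = 8.32e-06), with 5.14 ± 0.74 in D842V (n = 5) and 3.14 to 3.37 in the other 5 mutants. Foxf1, a mesodermal forkhead transcription factor gene, and its neighbouring long noncoding RNA Fendrr (adjusted p = 0.000237 for both) were highest in E7 del, at 6.78 ± 0.59 and 5.77 ± 0.63 (n = 3). The other named genes were Pyy, Sox21, Tm7sf2, Trpc4, Ucn3, Adamtsl1 and Hdac5, with adjusted p from 0.00989 to 0.0135. Neither Pdgfra (adjusted p = 0.184) nor Egfr (adjusted p = 0.455) passed this test. The count was 14 with the title range as a block, 0 within titles 41 to 64 and 222 within titles 1 to 30. It was 4 without D842V replicate 3 and 140 without E10 del.v2 replicate 2.

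D842V, a substitution in the kinase domain, was set against the other 5 mutants to see whether it stood apart. Pmch, the precursor of melanin-concentrating hormone, was 29.6-fold higher (log2 difference 4.89 ± 1.10, adjusted p = 0.0255), the choroid plexus gene Ttr 25.8-fold (4.69 ± 1.04, adjusted p = 0.0232) and the neuropeptide gene Ucn3 10.6-fold (3.40 ± 0.56, adjusted p = 0.000913). Pmch was 4.81 in D842V replicate 5 and 8.57 to 10.57 in the other 4, but also 11.76 and 11.15 in E10 del.v2 replicates 3 and 4 and 11.16 in C450 ins replicate 3. Ttr was 10.52 to 13.09 in D842V, and 13.42 in E10 del replicate 2, 13.28 in C450 ins replicate 3 and 12.82 in E10 del.v2 replicate 4. Cbln2, a synapse organiser, and Tnfsf11, the ligand of RANK, rose by 2.89 and 2.45. Tnfsf11 lost its call in 20 of the 36 fits that left out 1 array, and Cbln2 in 0. Rlbp1, which binds retinaldehyde, was 8.53-fold lower (-3.09 ± 0.65, adjusted p = 0.0151), and Susd5, the homeobox gene Meox1, the potassium channel gene Kcna5 and Lmcd1 were lower, with log2 differences of -2.95, -2.59, -2.13 and -2.12. In all, 69 genes were called, 37 higher and 32 lower.

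Immediate early genes, which respond quickly to growth factor and other stimuli, were higher in D842V, with 1 of 14 members risen, 13 not passing and 5 risen when adjusted over the list alone (camera adjusted p = 1.04e-08, adjusted p = 0.114 with an estimated correlation, fry adjusted p = 0.0159). Egr2 rose by 2.28 ± 0.41 (adjusted p = 0.00261), and Egr1 had a difference of 1.21 ± 0.33 (adjusted p = 0.0663). Myelinating oligodendrocyte genes were higher, with 1 of 18 members risen, Trf (1.40 ± 0.32), and 4 when adjusted over the list alone (camera adjusted p = 2.79e-08, adjusted p = 0.316 with an estimated correlation). Of the 12 ependymal and choroid plexus genes Ttr alone rose, and 4 rose when adjusted over the list alone (camera adjusted p = 0.00601, adjusted p = 0.583 with an estimated correlation). The 3 measured Hox genes fell only when adjusted over the list alone (camera adjusted p = 0.0166, adjusted p = 0.388 with an estimated correlation). Their mean was 2.73 ± 0.07 in D842V (n = 5) and 3.35 to 4.36 in the other mutant groups, all below the table median of 4.79. The neuron list mean was 8.72 ± 1.96 in D842V (n = 5). The D842V arrays all had titles 1 to 30. The block called 87 genes, 46 of the 69 among them, and lost Pmch, Ttr and Susd5 at differences of 4.57 ± 1.23, 4.34 ± 1.16 and -2.61 ± 0.74, while titles 1 to 30 alone called 385, 65 of the 69 among them, and lost Pmch (4.35 ± 1.33). The ependymal and choroid plexus list and the Hox list lost their calls in both (camera adjusted p from 0.074 to 0.445). The count was 705 with the host brain covariate, 207 without the 4 arrays lowest on component 1, and 10, 12, 12 and 15 without D842V replicates 2, 3, 4 and 5 in turn.

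In the comparison of E7 del with the other 5 mutants, Foxf1 was 6.71-fold higher (log2 difference 2.75 ± 0.34, adjusted p = 5.73e-06) and Fendrr 4.85-fold higher (2.28 ± 0.28, adjusted p = 5.73e-06). The helicase gene Ddx43, the phospholipid transporter gene Abcb4 and the cadherin gene Cdh15 rose by 2.24, 1.59 and 1.53. Resp18, found in neuroendocrine cells, was 21.3-fold lower (-4.41 ± 0.93, adjusted p = 0.0225), and the oligodendrocyte genes Aspa and Mal were 8.91-fold and 7.53-fold lower. Nkain2 and Gpr37 were lower, with log2 differences of -2.85 and -2.76. In all, 42 genes were called, 14 higher and 28 lower.

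Of 18 myelinating oligodendrocyte genes 4 fell in E7 del, 14 did not pass and 9 fell when adjusted over the list alone (camera adjusted p = 1.63e-08, adjusted p = 0.455 with an estimated correlation, fry adjusted p = 0.0463). They were Aspa, Mal, Mbp (-2.41 ± 0.53), which encodes myelin basic protein, and Mog (-2.69 ± 0.63). Of 15 cholesterol synthesis genes 2 fell, Fdft1 (-1.62 ± 0.31) and Stard4 (-1.41 ± 0.33), and 7 when adjusted over the list alone (camera adjusted p = 1.63e-08, adjusted p = 0.455 with an estimated correlation, fry adjusted p = 0.0463). The neuron list was lower with 0 of 18 members passing in either adjustment (camera adjusted p = 3.55e-07, adjusted p = 0.728 with an estimated correlation), and its mean was 6.31 ± 1.91 (n = 3). All 3 E7 del arrays had titles 41 to 64. The block called only Foxf1 and Fendrr, titles 41 to 64 alone called 0 genes, where Foxf1 differed by 2.10 ± 0.44 (adjusted p = 0.321), and the host brain covariate called 98, 11 of the 42 among them. The neuron list lost its call under the block (camera adjusted p = 0.114). The count was 4 or 5 without E7 del replicate 2 or 3, 85 without E7 del replicate 1, and 17 without the 4 arrays lowest on component 1. Cdh15 differed by 0.55 without E7 del replicate 1 and Mal by -1.89 without replicate 2, and they lost their calls in 28 and 26 of the 36 fits that left out 1 array.

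E10 del differed from the other 5 mutants in 94 genes, 23 higher and 71 lower. The growth regulators Cdkn2a, which encodes the INK4A and ARF tumour suppressors, and Mycn, a MYC family oncogene, were 7.29-fold and 5.01-fold lower (log2 differences -2.87 ± 0.63 and -2.32 ± 0.51, adjusted p = 0.0287 for both), and Creb5, Prokr1 and the chromatin remodeller gene Chd7 had differences of -1.98, -1.89 and -1.77. The largest rises were those of the cadherin gene Cdh9 (9.4-fold, 3.23 ± 0.78, adjusted p = 0.0391) and the neuropeptide Y receptor gene Npy2r (4.89-fold, 2.29 ± 0.49, adjusted p = 0.0287), and Epha6, the proapoptotic gene Hrk and Fibcd1 rose by 1.67, 1.65 and 1.43. Cell cycle genes were lower as a list with 0 of 24 passing and 23 fallen when adjusted over the list alone (camera adjusted p = 2.23e-08, adjusted p = 0.856 with an estimated correlation). Interferon response genes were lower with 0 of 15 passing and 13 fallen when adjusted over the list alone (camera adjusted p = 7.07e-06, adjusted p = 0.856 with an estimated correlation). Phlda1 (-1.08 ± 0.27) fell among the 20 MAPK feedback and output genes, and 9 fell when adjusted over the list alone (camera adjusted p = 0.000345, adjusted p = 0.856 with an estimated correlation, fry adjusted p = 0.0064). Neuron genes were higher with 0 of 18 passing in either adjustment (camera adjusted p = 1.03e-05, adjusted p = 0.856 with an estimated correlation).

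The neuron list mean was 10.64, 10.62 and 10.19 in E10 del replicates 1, 2 and 3, against 8.43 and 8.30 in replicates 4 and 5. Cdkn2a was 3.85, 4.30 and 4.46 in the former and 8.41 and 8.51 in the latter. Leaving out E10 del replicate 1, 2 or 3 gave 0 called genes each, leaving out replicate 4 or 5 gave 1615 and 1650, and without the 4 arrays lowest on component 1 limma called 0 genes and Mycn had a difference of 0.13. Cell cycle list means were 5.59, 5.82 and 5.24 in replicates 1, 2 and 3 and 8.3 and 8.25 in replicates 4 and 5. Without the 4 arrays 0 of the 8 lists kept their call, and 4 of them turned, the cell cycle list among these (0.14, camera adjusted p = 0.351). The title block, titles 1 to 30 alone and the host brain covariate also gave 0, and centring the arrays gave 52, 20 higher and 32 lower.

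**Figure D3:**
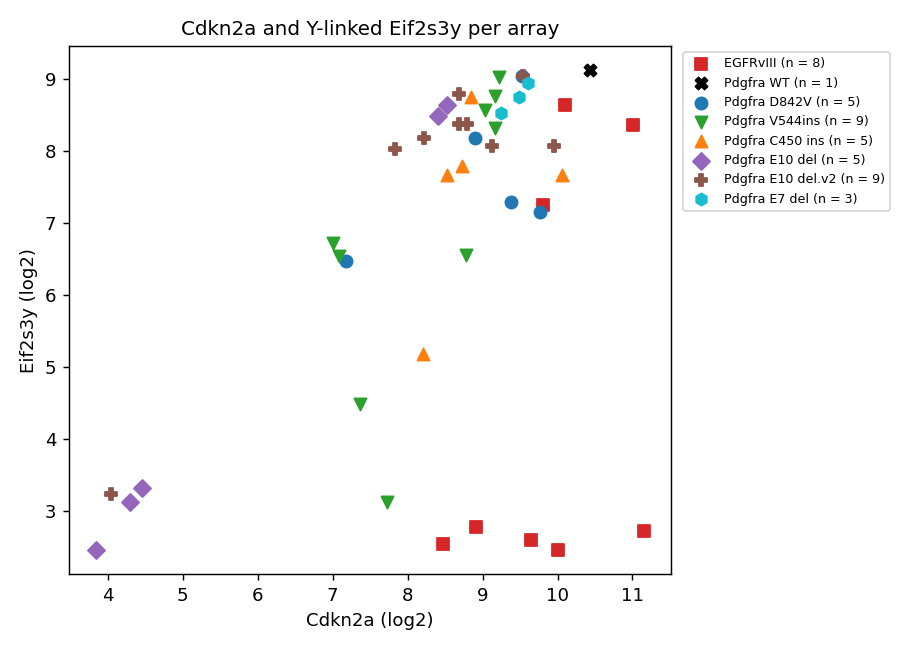
Log2 value of Cdkn2a (horizontal) and of the Y-linked gene Eif2s3y (vertical) in each of the 45 arrays, with a marker for each group. In the lower left, 3 E10 del arrays and E10 del.v2 replicate 2 have Cdkn2a at 4.46 or less, and 5 of the 8 EGFRvIII arrays have Eif2s3y at 2.77 or less with Cdkn2a at 8.47 or more.

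The 3 remaining mutants had 0 genes called by limma against the other 5, with 524 genes at an unadjusted p under 0.05 for V544ins, 432 for C450 ins and 709 for E10 del.v2. Lists still passed the camera test. Interferon response and myelinating oligodendrocyte genes were higher in V544ins as lists (camera adjusted p = 2.97e-07 for both, adjusted p = 0.543 with an estimated correlation), for example Irf7 with a difference of 1.15 ± 0.44 and Mog with 1.13 ± 0.41. Within titles 1 to 30 both lost their calls (camera adjusted p = 0.33 and 0.805), and 4 of the 10 lists of V544ins turned. Cholesterol synthesis and fibroblast matrix genes were higher in C450 ins (camera adjusted p = 9.9e-07 and 0.000755, adjusted p = 0.688 with an estimated correlation for both), with differences of 0.68 ± 0.21 for Dhcr7 and 2.32 ± 0.999 for Col3a1. The fibroblast matrix list mean was 9.35 in C450 ins replicate 5 and 6.45 to 7.45 in the other 4 arrays. Over all genes 0 members of these 4 lists passed, and Dhcr7 alone rose when adjusted over the list alone. The cholesterol list of C450 ins lost its call within titles 1 to 30 (camera adjusted p = 0.0575). Mesenchymal glioma markers were lower in E10 del.v2 with 3 of 25 fallen when adjusted over the list alone (camera adjusted p = 1.37e-07, adjusted p = 0.888 with an estimated correlation), and Tgfbi differed by -1.99 ± 0.56.

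E10 del and E10 del.v2, labels that differ only in an unexplained suffix, were compared directly. Limma called 0 genes, with 1385 at an unadjusted p under 0.05, so no gene was shown to differ. Pdgfra differed by -1.66 ± 0.66 (adjusted p = 0.403). Cell cycle genes were lower in E10 del as a list, with 0 of 24 passing in either adjustment (camera adjusted p = 2.23e-08, adjusted p = 0.939 with an estimated correlation). Without the 4 arrays lowest on component 1 that list had a median difference of 0.07 (camera adjusted p = 0.782), and 3 of the 6 lists turned. The gene count was 14 without E10 del.v2 replicate 2, and 8 and 4 without E10 del replicates 4 and 5.

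Arrays with titles 41 to 64 were compared with those with titles 1 to 30 within V544ins and E10 del.v2, to see what moved with the title numbers alone. Neuronal genes were lower in the upper range. The postsynaptic gene Ddn fell 12.2-fold (log2 difference -3.61 ± 0.72, adjusted p = 0.0183) and the serotonin receptor gene Htr2c 11.9-fold (-3.58 ± 0.84, adjusted p = 0.0293), and Spock3, the tachykinin gene Tac1 and the neuronal calcium sensor gene Hpca had differences of -3.44, -3.41 and -3.38. The ubiquitin ligase gene Trim25 and the RNA helicase gene Dhx58, both of the interferon system, rose by 1.86 and 1.45, and Tmprss5, Cdkn1c and Anxa6 by 1.5, 1.40 and 1.35. Of 18 neuron markers 5 fell, 13 did not pass and 13 fell when adjusted over the list alone (camera adjusted p = 5.97e-09, adjusted p = 0.921 with an estimated correlation), with differences of -2.93 ± 0.54 for Slc32a1 and -2.70 ± 0.58 for Gad2. Egfr was lower, with a difference of -0.97 ± 0.27 (adjusted p = 0.0436). Trim25, Dhx58, Tmprss5, Cdkn1c and Egfr lost their calls in 12, 14, 15, 16 and 14 of the 18 fits that left out 1 array. Anxa6 lost its call in 5, Ddn in 3, Htr2c in 6, Tac1 and Hpca in 5 each and Spock3 in 0. None of these genes turned. In all, 647 genes were called, 145 higher and 502 lower. Limma called 0 with the host brain covariate, 42 without E10 del.v2 replicate 1 and 3617 without E10 del.v2 replicate 2.

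Whether that difference between title ranges itself differed between V544ins and E10 del.v2 was tested as an interaction, which called 4 genes. Fam83d, whose protein acts on the mitotic spindle, had a difference of 2.32 ± 0.35 (adjusted p = 0.0299). Spink8 had -2.96 ± 0.37 (adjusted p = 0.00516), Eml2 -2.89 ± 0.45 and Hrk -2.36 ± 0.38 (adjusted p = 0.0301 for both). The count was 0 with the host brain covariate and 1138 without E10 del.v2 replicate 2.

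The array with unmutated PDGFRA lay nearer the mutant mean than the EGFRvIII mean at 623 of the 1061 genes that differed between them (58.7%), 258 of the 423 higher and 365 of the 638 lower in the mutants. Uty was 6.57, against at most 3.16 in the EGFRvIII arrays. Grik3 was 5.74, below all 36 mutant arrays, and Eif2s3y was 9.12, Arg1 7.16 and Cdkn2b 9.87, above them all (at most 9.03, 7.13 and 8.44). Its cell cycle list mean was 5.61 against a mutant mean of 7.81.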

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

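The counts of other splits for the mutants against EGFRvIII, for the F test, for V544ins and for E7 del, and the tests of explanations described here except the neuron list slope in E10 del, were chosen only after the result was seen. How the quartiles of each ratio were weighed against its bounds was also settled only after the values were seen.

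Array E10 del.v2 replicate 2 was far below the other 8 arrays of its group in 12 measures. Its list means were 7 for oligodendrocyte progenitor genes (next array 9.95), 4.82 for fibroblast matrix, 6.72 for neural stem, 8.06 for proneural, 5.24 for mesenchymal, 4.51 for cell cycle (next array 7.69), 7.05 for MAPK feedback and output and 6.29 for ERBB genes. In the same array Pdgfra was 4.16, Eif2s3y 3.23, Kdm5d 3.23 and Uty 3.08. E10 del.v2 replicate 8 was high in granulocyte genes (7.19), replicate 4 in ependymal and choroid plexus genes (6.03) and replicate 1 in immediate early genes (8.9). EGFRvIII replicate 7 was low in cell cycle genes (6.08). D842V replicate 1 was low in oligodendrocyte progenitor genes (8.57) and neural stem genes (7.42). D842V replicate 5 was low in neuron genes (5.33) and high in granulocyte genes (8.43) and fibroblast matrix genes (9.36), and D842V replicate 4 was high in immediate early genes (9.76). E10 del replicate 4 was high in NF-kB and inflammatory genes (6.4). C450 ins replicate 1 was low in oligodendrocyte progenitor genes (9.23), replicate 3 high in ependymal and choroid plexus genes (6.41) and replicate 4 high in Hox genes (6.31). Chance alone sets apart about 1 in 20 groups, which is 10.5 of the 210 tests made here, against 26 found. These tests are not independent, since lists share genes and 12 of the 26 came from E10 del.v2 replicate 2. The 2 counts therefore do not show an excess of arrays that stand apart.

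The difference between title ranges itself differed between V544ins and E10 del.v2, by the interaction test, for Spink8 (-2.96), Fam83d (2.32), Eml2 (-2.89) and Hrk (-2.36).

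The genes that differed between the PDGFRA mutants and EGFRvIII rested largely on EGFRvIII replicates 4, 5 and 6, which stood apart on component 2 from the other 5. Without these 3 arrays the median ratio of the log2 difference to the original was 0.481 (quartiles 0.263 and 0.714), the median absolute difference went from 0.72 to 0.30 at a mean standard error of 0.219 and 0.221, and 32 of the 1061 genes were still called, so that calls ended because differences shrank, though 1026 genes kept their sign. A host brain covariate left a median ratio of 0.791 (0.665 to 0.931) and 345 calls as the median absolute difference went to 0.55, and the title range as a block left 0.909 (0.745 to 1.09) and 245 calls at a median absolute difference of 0.63 and a mean standard error of 0.275. All 1061 signs were kept in both, and both ratios lay above the 0.25 that each explanation needs by more than their spread. For the host brain share this argues against it as the whole cause. The block cannot decide on the range as a cause, since its effect rests on V544ins and E10 del.v2 alone. There the range comparison moved from 647 to 3617 genes without E10 del.v2 replicate 2. The receptor label is the same in all 8 EGFRvIII arrays, so it does not account for the split between replicates 4, 5 and 6 and the other 5. How far the 1061 differences follow these 3 arrays or the driving receptor cannot be told, because the ratio lay between the bounds of 0.25 and 0.75. The biological difference between receptors, like differences between EGFRvIII tumours, stayed open and untested.

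The 94 genes that differed in E10 del may follow the content of the samples, since replicates 1, 2 and 3 had neuron list means of 10.19 or more and Cdkn2a of 4.46 or less. Eif2s3y was 2.45, 3.12 and 3.32 in these arrays and 8.48 and 8.64 in replicates 4 and 5. With the title range as a block the median ratio was 0.808 (quartiles 0.744 and 0.876) with all 94 signs kept, although all calls ended as the median absolute difference went from 0.87 to 0.68. The block cannot decide on the range as a cause, since its effect rests on V544ins and E10 del.v2 alone. There the range comparison went from 647 to 3617 genes without E10 del.v2 replicate 2. The neuron list slope in the other 5 mutants predicted a median of 0.236 of the observed differences (quartiles 0.149 and 0.3), far below the 0.75 needed, which argues against a linear trend with the neuron list as the whole cause. E10 del.v2 replicate 2, an array of another group with Cdkn2a at 4.05, differed from its own group by a median of 0.534 of the difference of the 3 arrays (0.268 to 0.729), with the same sign at 82 of 94 genes and at 80.8% of the other genes. The 2 remaining E10 del arrays showed a median of 0.394 of the difference (0.242 to 0.552) with 0 genes called by limma, at a mean standard error of 0.307 against 0.233. The receptor is the same in all E10 del arrays, so it does not account for the split between replicates 1, 2 and 3 and replicates 4 and 5. How far the 94 differences follow few tumour cells or the receptor cannot be told, since both ratios lay between their bounds.

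Y-linked transcripts were low in 5 of the 8 EGFRvIII arrays, with Eif2s3y at 2.77 or less against 7.25 or more in the other 3, while Uty was low in all 8. The lowest Cdkn2a value of those 5 arrays, 8.47, lay 4.01 above the highest of the 4 arrays lowest on component 1. This met the bound against few tumour cells as the cause, and argues against it, but rests on 1 gene. EGFRvIII replicate 1, which had that lowest value, had a neuron list mean of 10.29, against 10.19 or more in the 4 arrays. Few tumour cells is therefore not excluded for that array. In EGFRvIII replicates 3, 4 and 5 Eif2s3y (7.25 to 8.64) and Kdm5d (5.92 to 7.10) were high while Uty was 2.555 to 3.16. V544ins replicate 5 was alike, at 9.02, 6.95 and 3.14. These values argue against a female donor and loss of the whole Y chromosome as the cause of low Uty in those arrays. For the 5 arrays low in Eif2s3y, the sex of the astrocyte donors and loss of the Y chromosome remained open and were not tested.

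Other splits of the same arrays into groups of the same sizes showed how often chance gave as many genes. For the mutants against EGFRvIII 2 of 100 splits, the real one included, gave as many genes as the real 1061. The other reached 2536, which points to a structure of the samples beyond the groups. Few splits likewise reached the real count for the F test (2 of 100 splits, real 68, highest other 1156, again a sign of structure). The real split alone did so for D842V (1 of 100, real 69, highest other 0), E10 del (1 of 100, real 94, highest other 31) and E7 del (1 of 100, real 42, highest other 39). These splits mix the title ranges, and with the range as a block limma called 0 genes for E10 del and 2 for E7 del, and 0 for each within its own range. For the title ranges the real split alone reached its count (1 of 100, real 647, highest other 0), and for their interaction 3 of 100 did (real 4, highest other 540, a sign of structure). These shares were not corrected over the comparisons, so 2 or 3 of 100 splits do not exclude chance. For V544ins, C450 ins, E10 del.v2 and E10 del against E10 del.v2 limma called 0 genes (524, 432, 709 and 1385 at an unadjusted p under 0.05), so that all 100 splits gave as many by construction and say nothing about chance. The highest other splits there called 3145, 6, 2160 and 1 genes, and the values of 3145 and 2160 point to a structure of the samples.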

How the results depend on the processing

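Chosen after the data were seen were the tests with the neuron list as covariate, those without the 4 arrays lowest on component 1, those without the 3 EGFRvIII arrays apart on component 2, and the shuffles of array weights. Of 67 calls of named genes 67 were kept under quantile normalisation, 66 with a trended robust prior, 62 with centred arrays, 61 without a filter and 60 with the mean of probe sets, and 59 of the 59 that could be tested were kept with the stricter filter. The range as a block kept 25 of 52, titles 41 to 64 alone 10 of 32, titles 1 to 30 alone 9 of 20 and the host brain covariate 32 of 67. Without the 4 arrays 50 of 67 were kept and 1 turned, Mycn in E10 del, which went to 0.13, and without the 3 EGFRvIII arrays 6 of 22 were kept. Signal over background limited the tests through the filter, which left 11827 of 17097 genes. Where not stated otherwise the cause of a moved count was not tested. Comparisons are named here by their group, and counts that stayed within 1.5 times are left out.

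A minimum log2 difference of 1 gave 291 genes against EGFRvIII, 41 for D842V, 35 for E10 del and 357 for the title ranges, by its construction. No filter gave 106 for D842V, 80 for E7 del and 1 for E10 del against E10 del.v2, with more genes tested. Centred arrays gave 52 for E10 del. Array weights gave 10867 in the F test, 4678 for D842V, 4604 for V544ins, 2012 for C450 ins, 8418 for E10 del, 2248 for E10 del.v2, 6632 for E7 del, 7328 for E10 del against E10 del.v2, 5312 for the title ranges and 3759 for their interaction. With weights, shuffled labels called genes in 16 of 20 shuffles of the F test, up to 7351, and up to 7943 for E10 del, so these counts cannot be read as calls.

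The title range as a block gave 310 against EGFRvIII, 14 in the F test, 0 for E10 del and 2 for E7 del. Titles 41 to 64 alone, with fewer arrays, gave 79 against EGFRvIII, 0 in the F test and 0 for E7 del. Titles 1 to 30 alone gave 222 in the F test, 385 for D842V, 0 for E10 del, 1 for E10 del.v2 and 1 for E10 del against E10 del.v2. The host brain covariate gave 495 against EGFRvIII, 275 in the F test, 705 for D842V, 0 for E10 del, 98 for E7 del, 2 for E10 del against E10 del.v2, 0 for the title ranges and 0 for their interaction. Only the arrays compared gave 301 in the F test, 200 for D842V, 1 for V544ins and 213 for E7 del. The neuron list covariate gave 216 in the F test, 440 for D842V, 0 for E10 del, 3 for E10 del.v2, 142 for E7 del, 4 for E10 del against E10 del.v2, 0 for the title ranges and 1 for their interaction. Without the 4 arrays lowest on component 1 the counts were 36 in the F test, 207 for D842V, 0 for E10 del, 17 for E7 del, 3617 for the title ranges and 1138 for their interaction. Without the 3 EGFRvIII arrays 54 genes differed against EGFRvIII, and 2 when titles were also restricted to 41 to 64. All these counts are from limma, with 3256 genes at an unadjusted p under 0.05 against EGFRvIII, 2148 in the F test, 3270 for E10 del, 2007 for E7 del, 3166 for the title ranges and 3443 for their interaction in the fit without alternatives.

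Of the 11 lists that differed from EGFRvIII, 0 were called with an estimated correlation. Fry called 3 lists, 2 of the 11 among them, and the block and titles 41 to 64 alone called 6 each, all of the 11. The fit without the 3 EGFRvIII arrays called 4 lists, 3 of the 11 in their direction, and with titles 41 to 64 alone 4 lists, 1 of the 11 in its direction. The MAPK list was called in the same direction in every one of these except with an estimated correlation, with adjusted p from 1.17e-05 to 0.248 over all its alternatives. Without the 3 arrays 5 of the 11 lists turned, among them the oligodendrocyte progenitor list (-0.55, adjusted p = 0.00115), and 7 turned with titles 41 to 64 alone. The neuron list turned under the block (-0.21, adjusted p = 0.818) and the host brain covariate (-0.44, adjusted p = 0.0371), which holds the same genes, and the cholesterol list within titles 41 to 64 (-0.02, adjusted p = 0.864). Fry p-values are given above only for lists that fry called. In the other comparisons fry kept 1 of 11 lists for D842V, 1 of 8 for E10 del and 2 of 9 for E7 del. It kept 0 of 10 for V544ins, 0 of 9 for C450 ins and 0 of 9 for E10 del.v2. For E10 del against E10 del.v2 it kept 0 of 6, and for the title ranges 0 of 5.

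Leaving out 1 array at a time gave 186 to 2245 genes against EGFRvIII, with 186 without EGFRvIII replicate 5, 331 without replicate 6, 500 without replicate 4 and 2245 without replicate 1. The F test gave 4 to 140. Its values without D842V replicates 2, 3, 4 and 5 were 10, 4, 19 and 25, without E7 del replicates 1, 2 and 3 they were 136, 11 and 14, and without E10 del replicates 1 to 5 they were 25, 22, 45, 140 and 112. Without E10 del.v2 replicates 1, 2, 3, 5 and 6 they were 41, 140, 29, 31 and 45, and without V544ins replicate 2 the value was 111. D842V gave 10 to 133, with 10, 12, 12 and 15 without its replicates 2, 3, 4 and 5, 111 without E7 del replicate 1, and 133 and 115 without V544ins replicates 4 and 5. C450 ins gave 0 to 1, with 1 without its replicate 4 or D842V replicate 5, and V544ins and E10 del.v2 gave 0 throughout. E7 del gave 4 to 85, with 85, 4 and 5 without its replicates 1, 2 and 3, 26 without D842V replicate 1, 27 without C450 ins replicate 3 and 71 without V544ins replicate 7. E10 del against E10 del.v2 gave 0 to 14, with 14 without E10 del.v2 replicate 2, and 8 and 4 without E10 del replicates 4 and 5.

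E10 del gave 0 to 1650, with 0 without its replicates 1, 2 or 3, 1615 and 1650 without replicates 4 and 5, 886 without E10 del.v2 replicate 2, 240, 532 and 167 without V544ins replicates 1, 2 and 3, 414 without D842V replicate 1 and 350 without E7 del replicate 1. It gave 37 to 62 without D842V replicates 2 to 5, C450 ins replicates 3 to 5, E7 del replicates 2 or 3, V544ins replicates 4, 5, 6, 8 or 9, or E10 del.v2 replicates 1, 3 or 5 to 9. The title ranges gave 42 to 3617. Their values were 42, 3617, 217, 77, 235, 239 and 345 without E10 del.v2 replicates 1, 2, 3, 6, 7, 8 and 9, and 73, 43, 369 and 430 without V544ins replicates 1, 2, 8 and 9. The interaction gave 1 to 1138, with 1138 and 262 without E10 del.v2 replicates 2 and 5, 42 and 2 without V544ins replicates 3 and 5, and 1 without V544ins replicates 1, 2, 4, 6, 7 or 8 or E10 del.v2 replicates 3, 4, 6 or 8.

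The share of genes at which the array with unmutated PDGFRA lay nearer the mutants, 58.7%, was 57.8% to 60.2% under the probe set and scaling alternatives.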

Other observations

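The test of V544ins replicate 6 was written before its result was seen, and the hormone genes and the Mycn levels were singled out only after their values were seen.

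Some members of 3 lists that did not pass as a whole against EGFRvIII were called. In the neural stem and radial glia list, 1 of 17 members rose, 2 fell and 14 did not pass, while 1 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.13, adjusted p = 0.791 with an estimated correlation). The Notch target Hes1 (-0.97 ± 0.19) and Nes, which encodes the filament protein nestin (-0.92 ± 0.25), fell in the PDGFRA tumours, whereas Hes5, another Notch target, rose by 1.40 ± 0.36. Among classical glioma markers the Notch ligand gene Jag1 fell by 1.19 ± 0.30 and Nes was the other member to fall, while 2 rose and 4 fell when adjusted over the list alone. Col5a1 (-1.48 ± 0.33) and Fn1 (-1.26 ± 0.37), genes of the extracellular matrix, were the 2 of 18 fibroblast and collagen matrix genes to fall (camera adjusted p = 0.239, adjusted p = 0.896 with an estimated correlation), with 3 when adjusted over the list alone.

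Mycn, a named gene of E10 del, was 13.22 ± 0.23 in EGFRvIII (n = 8) and 10.37 ± 2.44 (n = 5) to 13.3 ± 0.26 (n = 3) in the mutant groups, and 13.45 in the array with unmutated PDGFRA. Its lowest values were 7.53 in E10 del and 9.13 in E10 del.v2. Cdkn2a was 10.44 in the array with unmutated PDGFRA and 9.89 ± 0.92 in EGFRvIII (n = 8).

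Pituitary hormone genes were high in a few arrays of different groups. Prolactin (Prl) was 13.54 in C450 ins replicate 5, 12.94 in V544ins replicate 4 and 10.9 in E10 del replicate 3, and growth hormone (Gh) was 13.03, 12.66 and 10.57 in the same arrays. Pomc was 12.23, 12.59 and 9.73 in these arrays, and 12.23 in E10 del replicate 2, where Prl was 6.36.

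The array with unmutated PDGFRA lay above all 36 mutant arrays in the interferon response list (10.03 against at most 9.91) and the unfolded protein response list (9.48 against at most 9.18), and marginally in the MAPK feedback and output list (8.37). It lay below them all in the pericyte and smooth muscle list (5.89 against at least 6.23) and the erythroid list (4.96 against at least 5.36). Its Hox list mean was 6.12 against a mutant mean of 3.59.

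V544ins replicate 6 had Eif2s3y at 3.12 and Uty at 2.999, levels like those of most EGFRvIII arrays. That it could be an EGFRvIII sample under another label was tested by its correlation across genes, which are not independent replicates, with group means. It was 0.127 with the other 8 V544ins arrays and -0.0802 with EGFRvIII, a difference of -0.207, which met the bound set before against this explanation. The explanation is still not excluded, because the EGFRvIII mean holds replicates 4, 5 and 6, which stood apart on component 2. No array of known group was put through the same test, so the spread of this difference is not known. Other causes were not tested.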
